A study of Oryza sativa with 4 samples.

How the data were processed

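Gene expression was measured in whole rice spikelets with the Affymetrix Rice Genome Array, a 1-colour oligonucleotide array in which each transcript is read by a set of short probes. Total RNA was turned into biotin-labelled cRNA, and 4 samples were hybridised to 1 array each. ZH11 (Zhonghua 11, a japonica cultivar) and plants of the same background carrying an RNA interference construct against OsCPK21 were each sampled at anther development stage 9 and stage 12. The labels name 3 RNAi lines, and whether their RNA was pooled was not given in the sources used here. There was 1 array per group, so no replicate spread, standard deviation or p-value could be computed, and the number of arrays limits the precision of every value. Groups followed the title, the description and the source name of each sample, which name the same genotype. The genotype characteristic names the opposite genotype on every sample. If that field were right, every direction between genotypes would turn.

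The deposited values were intensities on a linear scale, 1 signal per probe set and array, and MAS5 is the only tool named, per the submitters' processing notes. Its version, scaling target and detection calls were not given in the sources used here. The trimmed mean signal, leaving out 2% at each end, was 358 for RNAi at stage 9, 367 for ZH11 at stage 9, 333 for RNAi at stage 12 and 363 for ZH11 at stage 12, so the arrays lay near each other but at no common target. The median signals were 81.7, 85.0, 75.2 and 83.8 in the same order.

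The table held 57381 probe sets, of which 123 were controls and were left out of gene counts. The platform annotation used here gave 1 gene for 22436 probe sets, several for 95 and none for 34727. Probe sets with several genes or none were left out of gene counts. The remaining probe sets stood for 17905 genes, all of which were found in the RefSeq gene table of assembly ASM3414082v1, which was used for names only. Of these, 2457 had a symbol other than a bare locus number. Where several probe sets matched a gene, as for 3444 genes, the one with the highest mean log2 signal over the 4 arrays stood for it. A few symbols were replaced by the names in common use for the same locus, such as EAT1, RAFTIN1, OsC6 and OsC4.

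A floor was set at the mean trimmed mean of the 4 arrays divided by 5, a signal of 71.1, and lower signals were raised to it before log2 was taken. A gene was counted as higher or lower where its ratio was at least 2-fold and the brighter array was above the floor. A ratio with 1 array at or below the floor is given as a bound, and no fold is given where both were. Genotypes were compared at each stage, and stages within each genotype. The difference of the genotype ratios between stages was taken per gene. Overlaps of gene counts are given beside the value for independent lists. For overlaps that share an array, they are also given beside the mean of 100 simulations, whose noise was drawn from the genotype ratios at stage 9. The simulations held neither a genotype nor a stage effect, since each gene had its mean level on all 4 arrays. They therefore cannot show what the shared array gives in data with a stage change. Within genes, the log2 genotype ratios of probe sets had an SD of 0.285 at stage 9 and 0.421 at stage 12, so noise from stage 9 may be too narrow for stage 12. The simulations were therefore repeated with noise from the stage 12 genotype ratios, which hold the differences themselves and may be too wide. This was added after the results were seen, as was the choice of genes seen only at stage 12 by the RNAi signal or by the mean of both genotypes.

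Gene lists were fixed before the data were examined. They covered tapetum and pollen wall genes, meiosis genes, MIKC* MADS-box genes of late pollen, floral organ identity genes (stamen identity genes among them) and beta-expansins. Pectin-modifying enzymes, actin cytoskeleton genes, calcium-dependent protein kinases and calmodulin and CBL calcium sensors were covered as well. Further lists held calcium channels and pumps, ROP GTPase and NADPH oxidase genes, RALF and arabinogalactan genes, and sugar transporters with invertases and hexokinases. Others held starch synthesis enzymes, photosynthesis genes, histones, cytosolic ribosomal proteins, heat shock proteins, and peroxidases with glutathione S-transferases. The list of jasmonate genes was fixed at the same time. The gene table held no descriptions or RAP identifiers. Members named one by one were therefore matched by symbol and chromosome: 55 symbols were asked for, 41 were found in the table and 36 were on the array. Members sought by description were matched by patterns on symbols, written before single genes were looked at. Alpha-expansins, aquaporins, cyclins with DNA replication genes, and the cellulose synthase family were added in that step. A total of 20 members were removed after list results had been seen, because their other names are those of another kind of protein (actins among the ROP genes, homeobox genes among the histones, BRI1-interacting proteins among the heat shock proteins). Lists of PP2C protein phosphatases, RAB16 and LEA genes, and WRKY transcription factors were chosen after single-gene values had been seen. Each list of at least 3 measured members was described by its median log2 ratio, its members past 2-fold, and the percentile of its median among 10000 random gene lists of the same size matched on mean signal, as a description of these arrays.

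The genes named were set by a rule fixed before the data were examined: OsCPK21 in every array, and, for each comparison, among genes with an informative symbol, the 10 largest ratios in each direction among those above the floor on both arrays. The rule added the 5 brightest in each direction among those at or below the floor on the other array, the 3 members of each list with the largest ratios, and every member of lists of 5 or fewer. Other genes named to spell out a count were chosen after their values were seen.

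Alternatives set beforehand were a floor at 0.5 and at 2 times the main one, a pseudocount of 23.7 in place of the floor, scaling of each array to a common median, quantile normalization, the mean over a gene's probe sets, leaving out probe sets with IDs ending in _x_at or _s_at, and a 3-fold threshold for counts. Counts over all non-control probe sets and the lists before the removal of members were added after seeing the data. The counting and list steps were tested on simulated data for the stage 12 genotype comparison, with 17905 genes, 200 of them changed and an assumed noise SD of 0.25 on the log2 scale. A 2-fold change was recovered for 44.5% of the changed genes, a 4-fold change for 100% and a 16-fold change for 98%, and 81, 68 and 55 unchanged genes were called. Of 40 simulated lists without a shift, 4 fell outside the central 95% of random lists. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.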

Results

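OsCPK21 encodes a calcium-dependent protein kinase, one of the plant enzymes that bind calcium directly and phosphorylate other proteins. The series set spikelets in which it was silenced by RNA interference against spikelets of ZH11, the parent cultivar, to ask how the kinase bears on pollen development. Spikelets were taken at anther stage 9, when young microspores have been freed from their tetrads and the tapetum that feeds them is active, and at stage 12, when pollen matures. Each of the 4 groups (RNAi and ZH11 at each stage) was 1 array, so the values have no replicates and none of the differences could be tested. "Higher" and "lower" mean a ratio of at least 2-fold with the brighter array above the floor. At stage 9, 14981 of 17905 genes were above the floor in RNAi and 15072 in ZH11, and at stage 12 these were 15304 and 15569. Across genes, which are not independent replicates, log2 signals of the genotypes had a Pearson correlation of 0.963 at stage 9 and 0.894 at stage 12. The stages had one of 0.710 in ZH11 and 0.778 in RNAi.

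The target gene was low in both arrays titled RNAi. OsCPK21 (LOC4346187, read by 1 probe set) had a signal of 1939.6 in ZH11 and 206 in RNAi at stage 9, 9.41-fold lower. At stage 12 it had a signal of 2719 in ZH11 and 17.6 in RNAi, below the floor of 71.1, which made it at least 38.3-fold lower. Its level therefore went with the titles and against the genotype characteristic, which names the other genotype on all 4 samples. The directions given here follow the titles. All would turn if that characteristic were right.

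**Figure D1:**
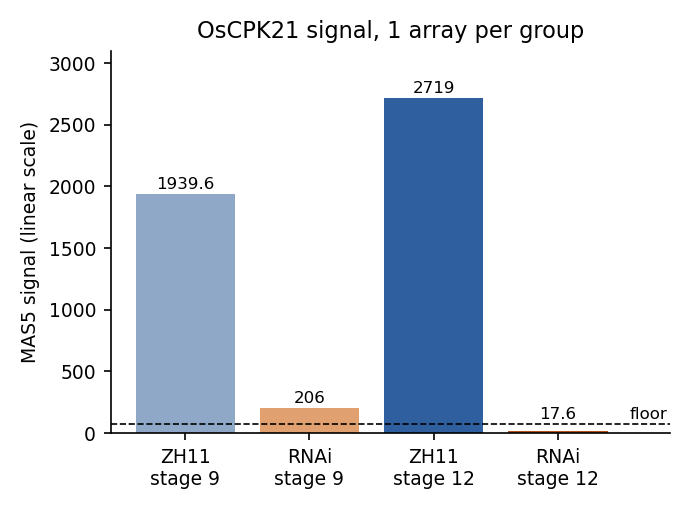
MAS5 signal of OsCPK21 on a linear axis, 1 bar per array and 1 array per group, with the floor of 71.1 as a dashed line. The RNAi bars stand at 206 and 17.6, and the ZH11 bars at 1939.6 and 2719.

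At stage 9, 10 of 33 measured jasmonate genes were higher in RNAi spikelets and 5 of 12 tapetum and pollen wall genes were lower. JAZ13, a member of the family of jasmonate-induced repressors, was 58.0-fold higher in RNAi, JAZ12 was 17.8-fold, JAZ11 10.9-fold and JAZ10 8.70-fold higher. OPR4 and OPR1, of the oxophytodienoate reductase family that includes an enzyme of jasmonate synthesis, were 8.86-fold and 7.25-fold higher. OsC6, a lipid transfer protein of the tapetum, was at least 123-fold lower, with a signal of 8767 in ZH11 and none above the floor in RNAi. In all, 504 genes were higher and 348 lower in RNAi, 5.55% of the 15358 genes above the floor on either array.

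Of the 33 jasmonate genes 1 was lower at stage 9, and the list had a median log2 ratio of 0.06 at percentile 99.6 of matched random lists. Of its 13 JAZ genes, 7 were higher, and JAZ2 went the other way, 8.54-fold lower. AOS (LOC4334233), which acts early in jasmonate synthesis, had a log2 ratio of 1.54. WRKY71, a transcription factor of defence responses, was 31.8-fold higher and BHLH148, which binds JAZ proteins, at least 54.2-fold. MYB2 was at least 11.7-fold, BC1L9 at least 24.6-fold, the heat stress factor HSF07 9.88-fold and the protein phosphatase OsPP2C29 13.5-fold higher. PAL06, of the phenylalanine ammonia-lyase family, was 7.84-fold higher and the membrane protein gene OsPM19L1 at least 6.93-fold, although its other probe set had a log2 ratio of 0. Heat shock proteins counted 5 higher and 2 lower among 26, with a median of 0.26, above all 10000 matched random lists. The higher ones were HSP24.1, at least 9.46-fold, HSP17.4, 5.46-fold, HSP17.8, 2.75-fold, CLPB1, 2.06-fold, and HSP18.6, with a log2 ratio of 1.32. HSP18.8 and HSP17.9B were lower, with log2 ratios of -1.04 and -1.11. HSP18.8 fell within 2-fold under median scaling and with a pseudocount, CLPB1 with a pseudocount, and HSP17.8 at 2 times the floor.

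Of 12 tapetum and pollen wall genes, 5 were lower at stage 9 and 1 was higher, with a median of -0.34 at percentile 0.08 that was -0.80 without cross-matching probe sets. Besides OsC6, EAT1, a bHLH factor of tapetal cell death, was 3.94-fold lower, RAFTIN1, a sporopollenin-associated protein, 2.68-fold lower, and the aspartic protease AP25, a target of EAT1, 2.34-fold lower. CP1, a cysteine protease, had a log2 bound of -1.31. PTC1, a PHD-finger regulator of the tapetum, was 2.20-fold higher, while TDR (log2 0.33), CYP703A3 (-0.32) and OsC4 (-0.37) were within 2-fold. Outside the list, HXK6 (LOC4338010), a hexokinase, was 18.8-fold lower and CHS1, of chalcone synthase, which starts flavonoid synthesis, 17.6-fold lower, although the log2 ratios of its 5 probe sets ran from -4.14 to 0. NIP4-1, an aquaporin-family channel, was at least 31.6-fold lower, ASMT3 was 4.45-fold and the glucanase GLU15 4.79-fold lower, and the lectin gene ML was 4.26-fold lower. The glutathione S-transferase GST1 was 3.62-fold and ERG1 3.51-fold lower, and MT1B, a metallothionein, at least 3.70-fold. The formin FH10 was at least 5.15-fold lower and HIRL2 at least 4.28-fold.

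Calcium genes other than the target were mostly within 2-fold at stage 9. Of 20 calcium-dependent protein kinases, OsCPK21 was lower and CPK4 was 2.49-fold higher. Among 55 calmodulin and CBL sensors and their kinases 4 were higher: CML31, 8.67-fold, CML32, at least 5.51-fold, CIPK21, 2.63-fold, and CML27, with a log2 ratio of 1.25. The median was -0.07 at percentile 18.8. Among 10 calcium channels and pumps ACA7, a calcium ATPase, was 6.57-fold higher. None of the 6 meiosis genes passed 2-fold; their median was 0.32 at percentile 98.9, with DMC1, the meiotic recombinase, at a log2 ratio of 0.53 and PAIR2 at 0.34. The floral organ identity and photosynthesis lists had negative medians. The 17 floral organ identity genes had one of -0.19 (percentile 1.81) and the 8 photosynthesis genes one of -0.33 (percentile 0.29), none past 2-fold. The floral list includes stamen identity genes such as MADS3, its lowest member with a log2 ratio of -0.71, so it does not stand for tissues outside the anther alone.

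Medians of further lists at stage 9 were small. Beta-expansins, cell wall proteins that include grass pollen allergens, had a median of -0.38 at percentile 0.18 over 10 genes, none past 2-fold. The 8 ROP GTPase and NADPH oxidase genes had a median of -0.23 (percentile 2.90), and the 22 cytosolic ribosomal proteins one of 0.07 (percentile 99.9), none past 2-fold in either. Among 28 actin cytoskeleton genes the formin FH16 was 2.35-fold higher and FH10 was lower. HXK6 was the one of 29 sugar genes past 2-fold. GST1 and a peroxidase (LOC4339222) were lower among 15 peroxidases and glutathione S-transferases, whose median was -0.17. The 7 starch enzymes (median 0.04) and the 5 histones measured, all H2B genes (median 0.08), held no gene past 2-fold.

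**Figure D2:**
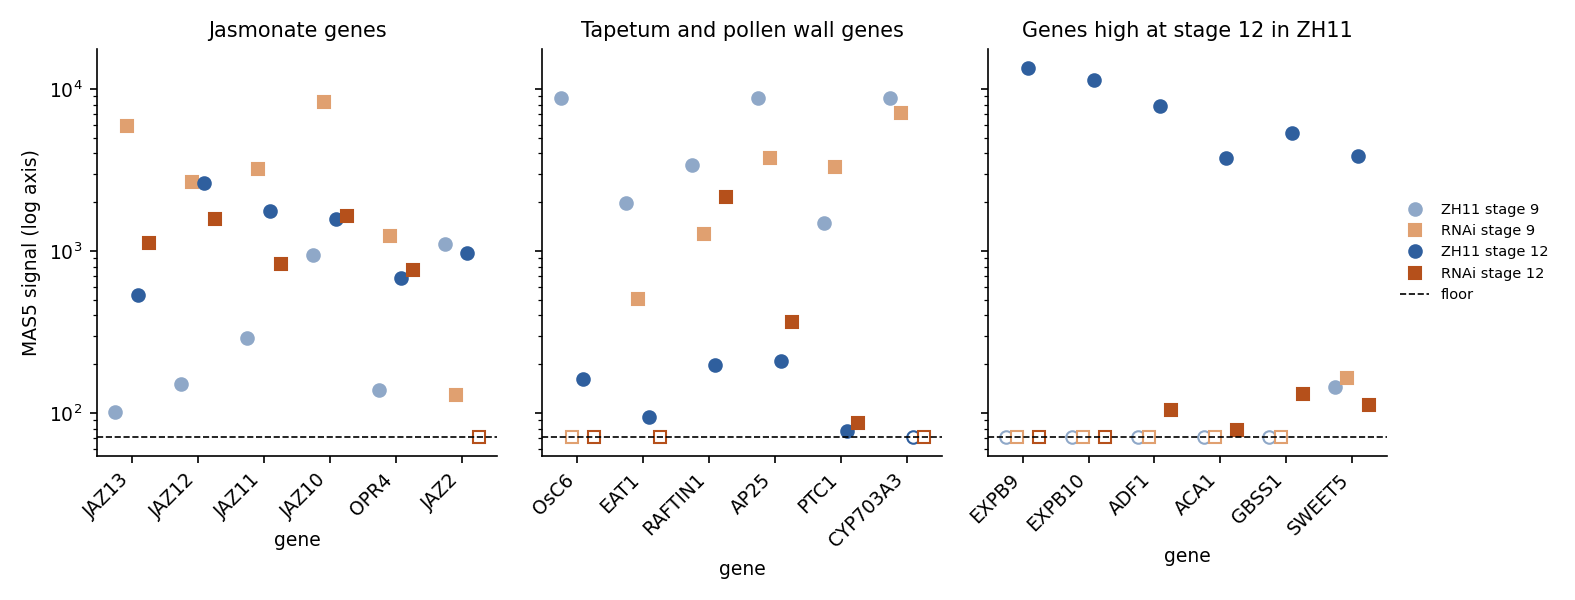
MAS5 signal on a log axis of 18 named genes in each of the 4 arrays, with circles for ZH11, squares for RNAi, light colours for stage 9 and dark ones for stage 12. Open symbols are signals at or below the floor (dashed line), drawn at it. At stage 9 the JAZ genes other than JAZ2 stood higher in RNAi, and in the panel of genes high at stage 12 in ZH11 the RNAi signals stood at 165 or below at both stages.

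At stage 12 more genes were lower than higher in RNAi spikelets, many of them at the floor there. EXPB9 and EXPB10, beta-expansins of grass pollen, had signals of 13529 and 11378 in ZH11 and none above the floor in RNAi, at least 190-fold and at least 160-fold lower. ADF1, an actin-depolymerizing factor, was 74.7-fold lower, ACA1, a calcium ATPase, 47.5-fold, GBSS1, the granule-bound starch synthase of the waxy locus, 41.0-fold and the sugar transporter SWEET5 34.6-fold lower. The 6 probe sets of GBSS1 had log2 ratios from -5.36 to 0.18. In all, 1122 genes were lower and 455 higher in RNAi, 9.88% of 15966 genes above the floor on either array. By 4-fold or more, 524 were lower and 40 higher, and by 16-fold or more 221 were lower and none higher. Of the lower genes, 406 were at or below the floor in RNAi.

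The balance of higher and lower genes at stage 12 moved with the scaling. The higher genes were 28.9% of those called on the deposited scale, 41.2% (674 higher, 962 lower) with arrays scaled to a common median and 39.4% (638 higher, 980 lower) after quantile normalization. These scalings moved the median log2 ratio of the genes above the floor on both arrays by 0.15 and 0.13. Under both, the lower members went from 4 to 2 in the jasmonate list, from 4 to 3 among beta-expansins, from 7 to 6 among sugar genes and among calcium sensors, and from 6 to 5 among actin cytoskeleton genes, and 1 photosynthesis gene and 1 calcium channel or pump came to be higher. In the lists added later, the higher members went from 7 to 9 among PP2C protein phosphatases and from 1 to 2 among cyclins and DNA replication genes. Also, 1 alpha-expansin came to be higher.

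Several other genes at the head of the stage 12 ranking stood near or below the floor in RNAi. YSL7, of a family of metal-chelate transporters, was at least 115-fold lower, NifU1, of iron-sulphur cluster assembly, at least 83.5-fold and ADF6 at least 66.8-fold, although the other probe set of NifU1 had a log2 ratio of 0. The kinases CIPK5 and MPK17 were 42.3-fold and 30.7-fold lower. RTS, an anther gene needed for male fertility, was 21.2-fold lower, CPS1, of diterpene synthesis, 17.7-fold, CML32 17.5-fold and the maltose transporter MEX1 12.7-fold lower. The higher genes at stage 12 were fewer. RAB21 was 14.1-fold higher, PP2C68 and PP2C30, protein phosphatases of abscisic acid signalling, 10.3-fold and 4.62-fold, DREB1B, a transcription factor of cold and drought responses, 6.21-fold, and RAB16B and DREB1E at least 2.89-fold and 2.85-fold. RAFTIN1 was 10.8-fold higher, LTP-2, a lipid transfer protein, 8.20-fold, CML14 7.20-fold, CAD7, of lignin synthesis, 6.14-fold, the aquaporin OsPIP1;3 5.66-fold and RFS 4.51-fold higher. The germin-like genes GER2 and GER1 were at least 5.89-fold and 4.67-fold higher.

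Among 10 beta-expansins, 4 were lower and 1 was higher at stage 12, with a median of -0.35 at percentile 0.82 (-0.61 without cross-matching probe sets). EXPB2 was 3.52-fold and EXPB8 2.03-fold lower beside EXPB9 and EXPB10, and EXPB3 was 2.68-fold higher. Of 29 sugar transporters, invertases and hexokinases 7 were lower and 1 was higher, with a median of -0.28 at percentile 0.06. Among them MST5, a monosaccharide transporter, was at least 24.9-fold and SWEET15 at least 8.0-fold lower, and SWEET16 was 2.04-fold higher. The hexokinases HXK5 and HXK2 (LOC4339420) were among the lower members, with log2 ratios of -1.92 and -1.43. Of 28 actin cytoskeleton genes 6 were lower. They included VLN4, a villin, at least 57.6-fold lower, ADF9, with a log2 bound of -5.74, and the bright actin gene ACT1, with a log2 ratio of -1.42, and the formin FH8 was higher. The median of -0.05 turned sign under median scaling. The actin control probe set at the 3-prime end was lower too, with a signal of 9651 in ZH11 and 2904 in RNAi. The ratio of 3-prime to 5-prime signal, a measure of RNA integrity, was 10.3 in ZH11 and 8.53 in RNAi for actin and 3.48 in both for Gapdh.

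Calcium genes were among those lower at stage 12. Of 20 calcium-dependent protein kinases 5 were lower and none higher: OsCPK21, CPK2 (at least 42.6-fold), CPK22 (at least 39.1-fold), CPK29 (at least 35.3-fold) and CPK6, with a log2 bound of -4.54. Of these, CPK2, CPK22 and CPK29 were at or below the floor on both stage 9 arrays. The list's median, -0.03, turned sign under both other scalings. Of 55 calmodulin and CBL sensors and their kinases 7 were lower and 4 higher, with a median of 0.00 at percentile 46.0. CIPK30 was at least 27.9-fold lower, and CML14, CML31, CML16 and CIPK6 were higher, by 2.85, 1.69, 1.45 and 1.16 on the log2 scale. ACA1 was the one of 10 calcium channels and pumps past 2-fold. Among 8 ROP GTPase and NADPH oxidase genes RAC6 was 4.10-fold lower, against a list median of 0.39 at percentile 99.5.

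Jasmonate genes stood on the other side at stage 12, with 4 lower and 1 higher of 33 and a median of -0.29 at percentile 0.02. JAZ2 was at least 13.6-fold, JAZ9 6.27-fold, JAZ11 2.14-fold and COI2, a jasmonate receptor family member, 2.17-fold lower, while JAZ13 was 2.08-fold higher. JAZ11 and COI2 were within 2-fold under both other scalings, with log2 ratios of -0.95 and -0.96 under median scaling. Of the 12 tapetum genes RTS and OsC6 (at least 2.28-fold) were lower and RAFTIN1 was higher, and the median of -0.01 turned sign under both other scalings. None of the meiosis genes (median -0.09), the floral organ identity genes (median 0.17, percentile 95.7), the photosynthesis genes (0.03), the histones (0.18) or the starch enzymes (-0.22, percentile 7.24) passed 2-fold. The symbol patterns of the starch list missed GBSS1, which was lower. CLPB1 was the one heat shock gene past 2-fold, 2.02-fold higher, with a list median of 0.11. The ribosomal proteins had a median of -0.15 at percentile 1.18, which turned to 0.0064 under median scaling. Among peroxidases and glutathione S-transferases the peroxidase LOC4339222 was 2.42-fold lower. The pectin list held only PMEI8 and PMEI28, symbols of pectin methylesterase inhibitors, so no pectin-modifying enzyme was matched. Both were below the floor at stage 12 in both genotypes and had log2 ratios of 0.37 and -0.18 at stage 9. AGP1, the one arabinogalactan gene measured, had log2 ratios of 0.09 at stage 9 and 0.45 at stage 12. No MIKC* MADS-box gene of late pollen was matched, and OsMADS62, OsMADS63 and OsMADS68 were not analysed here.

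Between stages, 10 of 12 tapetum genes were lower at stage 12 in ZH11 spikelets. Signs of RNA quality moved with stage too: the 3-prime to 5-prime ratio was 3.89 at stage 9 and 10.3 at stage 12 for actin, and 1.96 and 3.48 for Gapdh, and the 18S rRNA control had signals of 5522 and 2193. OsC4, a lipid transfer protein of the tapetum, was at least 178-fold lower at stage 12 than at stage 9, CYP703A3, a hydroxylase of sporopollenin synthesis, at least 125-fold, OsC6 54.0-fold, AP25 41.9-fold and EAT1 21.0-fold lower. EXPB9 and EXPB10 were at least 190-fold and 160-fold higher at stage 12, ADF1 at least 110-fold, NifU1 at least 83.5-fold and GBSS1 at least 75.7-fold. YSL7 was 62.5-fold, ADF6 57.6-fold and SWEET5 26.5-fold higher. The counts were 2804 genes higher and 2574 lower at stage 12. In the tapetum list RTS was 20.2-fold higher, and the list had a median of -4.18 below all 10000 matched random lists. The ROP list had 7 of 8 lower, with RAC2 18.6-fold and RAC7 11.8-fold lower and a median of -1.98 at percentile 0.01. Sugar genes had 15 of 29 higher and 2 lower, with a median of 1.02 above all matched random lists (0.43 at 2 times the floor). Jasmonate genes had 10 higher and 1 lower, with a median of 0.62 at percentile 99.96 (0.31 at 2 times the floor), JAZ12 being 17.4-fold and JAZ11 6.09-fold higher. WRKY71 was 24.0-fold and GH3-8, of a family that conjugates auxin, 24.4-fold higher, CML1 26.1-fold, SMR1 25.8-fold, CYP701A8 and GER6 both 23.6-fold and the aquaporin TIP1 22.4-fold higher. Photosynthesis genes had 5 of 8 higher, RBCS, the small subunit of Rubisco, by 7.99-fold, PSB28 by 3.38-fold, GOS5 by 2.66-fold, LFNR1 by 2.34-fold and PSAG by 2.32-fold. Further genes lower at stage 12 were GER5 (at least 50.9-fold), the expansin EXP16 (at least 42.8-fold), CYCP2-1 (34.1-fold), BURP3 (29.8-fold) and NIP4-1 (27.5-fold).

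In RNAi spikelets the tapetum genes were lower at stage 12 as well, but several of the genes with the largest ratios in ZH11 were not higher. The 3-prime to 5-prime ratio was 4.20 at stage 9 and 8.53 at stage 12 for actin, and 2.5 and 3.48 for Gapdh, and the 18S rRNA control had signals of 4961 and 1579. CYP703A3 was at least 100-fold lower, OsC4 82.9-fold, PTC1 37.7-fold, GER5 at least 50.3-fold, EXP16 30.3-fold, BGLU30 at least 24.7-fold and PCF5 19-fold lower. EXPB9, EXPB10, NifU1 and ADF6 were at or below the floor at both stages, SWEET5 was 1.48-fold lower at stage 12, and ADF1 and GBSS1 were above the floor by 1.48-fold and 1.85-fold. Among the genes named, large ratios upwards were seen in the chitinase genes Cht4 (at least 54.4-fold), chia4a (at least 40.4-fold) and Cht2 (at least 33.9-fold). ASMT3 was 44.8-fold, CHS1 44.5-fold, MT-1, a metallothionein, 42.6-fold and GLU15 40.4-fold higher, HOX24 at least 35.8-fold and BURP17 at least 35.0-fold. CML1 was 25-fold, SMR1 23.7-fold, ML 20.2-fold, LTP 19.8-fold and CIN1, a cell wall invertase, 19.4-fold higher. Not all of these were particular to RNAi. Cht2 had genotype log2 ratios of 0 at stage 9 and 0.14 at stage 12, and CML1 had stage log2 ratios of 4.70 in ZH11 and 4.64 in RNAi. The genotype log2 ratio of CHS1 was -4.14 at stage 9 and 0.07 at stage 12, so its rise drew on a low stage 9 signal in RNAi. Its 5 probe sets ran from -4.14 to 0 there. ASMT3 and GLU15 were lower in RNAi at stage 9 as well. The counts were 2400 genes higher and 2535 lower. The balance turned to 2731 higher and 2264 lower under median scaling and to 2655 and 2306 under quantile normalization, which moved the median of the genes above the floor on both arrays by 0.12 and 0.10. The tapetum list had 7 lower of 12 and none higher, with a median of -2.97 below all matched random lists, and RAFTIN1 had a log2 ratio of 0.75. The ROP list had 6 of 8 lower, with a median of -1.75 at percentile 0.03 (-1.11 before the removal of members). The sugar list had 11 higher and 3 lower and a median of 0.00. The jasmonate list had 1 higher and 8 lower, with a median of -0.35 at percentile 0.92. Floral organ identity genes had 4 higher and 1 lower of 17, with MADS13, an ovule identity gene, 11-fold higher in RNAi and 9.49-fold in ZH11, and a median of 0.68 at percentile 99.9 (0.28 at percentile 95.3 in ZH11). Photosynthesis genes had a median of 1.18 in RNAi and 1.22 in ZH11. Calmodulin and CBL sensors had 10 higher and 15 lower in RNAi, with a median of -0.44 at percentile 0.02, and 16 higher and 12 lower in ZH11, with a median of -0.05.

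The genes lower in RNAi at stage 12 were largely those higher at stage 12 in ZH11. Of the 1122, 830 (74.0%) were also higher at stage 12 than at stage 9 in ZH11, EXPB9, ADF1, ACA1, CIPK5, GBSS1, SWEET5 and MPK17 among them. Independent lists of these sizes would share 176. Both lists hold the ZH11 stage 12 array, so part of the excess may come from that array. Simulations with neither a genotype nor a stage effect shared 217 on average and 256 at most. With noise drawn from the stage 12 genotype ratios they shared 436 and 477. Lacking the stage change, the simulations cannot size the part of the shared array. Of the 455 genes higher in RNAi at stage 12, 177 were lower at stage 12 than at stage 9 in ZH11, against 65.4 for independent lists. The simulations gave 163 on average and 191 at most, and 250 on average with stage 12 noise. The shared array may give this overlap, but simulations without a stage change cannot decide it. Another 99 were higher at stage 12 in ZH11 as well, against 71.3 for independent lists. The simulations gave 5.31, and 15.9 with stage 12 noise. Without a stage effect they hold few such genes by their setting, so they are no measure for this overlap. A set of 321 genes was at or below the floor on both stage 9 arrays and at least 8 times the floor in ZH11 at stage 12. Of these, 228 (71.0%) were lower in RNAi, 163 of them by 16-fold or more, 85 were within 2-fold and 8 were higher, and their median log2 ratio was -4.05. A choice by the ZH11 signal favours genes lower in RNAi. Of 131 genes chosen in the same way by the RNAi signal 29 were higher and 4 lower, and of 173 chosen by the mean of both genotypes 68 were lower and 15 higher, with a median of -0.34. In both genotypes 1639 genes were higher and 1838 lower at stage 12, against 376 and 364 for independent lists.

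**Figure D3:**
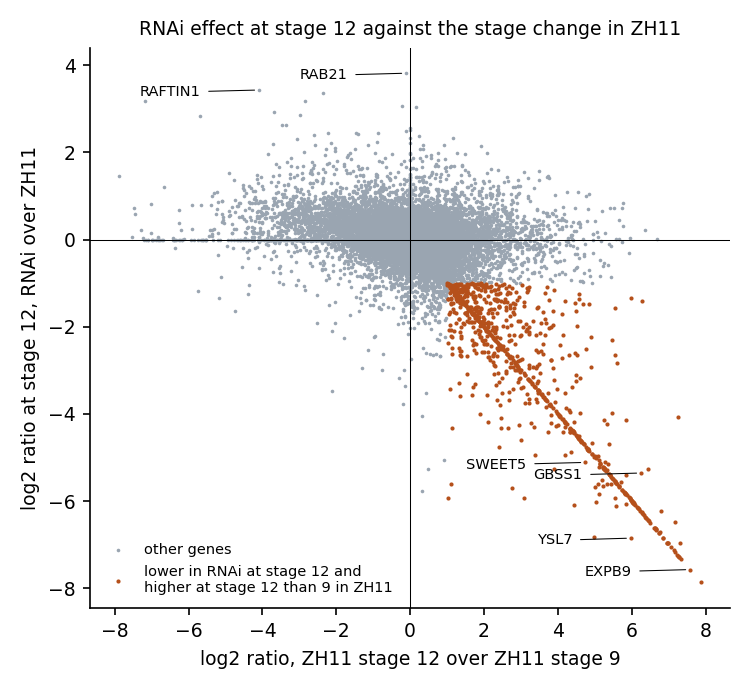
Log2 ratio of RNAi over ZH11 at stage 12 (vertical axis) against log2 ratio of stage 12 over stage 9 in ZH11 (horizontal axis), 1 point per gene. The 830 genes in orange were lower in RNAi at stage 12 and higher at stage 12 than 9 in ZH11; genes at the floor on the other arrays fall on the diagonal because both ratios then hold only the ZH11 stage 12 signal.

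The genotype ratios of the stages were also set against each other. JAZ13, BHLH148, BC1L9, MYB2, OsPP2C29, CML31, RFS, DREB1B, PP2C68, PP2C30, CLPB1, CYCD2-2 and RAB16B were higher in RNAi at both stages, and OsCPK21, JAZ2, OsC6 and the peroxidase LOC4339222 lower at both. Some of these hung on the settings. At 2 times the floor OsC6, CYCD2-2 and RAB16B fell within 2-fold at stage 12. With a pseudocount CLPB1 did at both stages and PP2C30 at stage 9. In all, 106 genes were higher at both stages, against 12.8 for independent lists, and 42 were lower at both, against 21.8. Another 27 were higher at stage 9 and lower at stage 12, against 31.6, and 20 went the reverse way, against 8.84. The log2 ratio of RNAi over ZH11 differed by at least 1 between the stages for 2466 genes, 962 with the larger value at stage 12 and 1504 with the larger value at stage 9. With 1 array per group this difference could not be tested.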

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

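All tests of explanations given here were chosen after the results were seen, except the one on the share of pollen RNA, which was set before its value was known but whose reading was changed afterwards.

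For 7 named genes the genotype ratio lay past 2-fold in opposite directions at the stages, and with 1 array per group the difference was not tested. RAFTIN1 was lower in RNAi at stage 9 and higher at stage 12, a difference of 4.85 on the log2 scale, and so were GLU15 (3.28) and ERG1 (2.88). CML32, GH3-8, JAZ11 and JAZ9 were higher in RNAi at stage 9 and lower at stage 12, with differences of -6.59, -5.12, -4.55 and -4.19, although JAZ11 at stage 12 fell within 2-fold under both other scalings and ERG1 at 2 times the floor and with a pseudocount. Probe sets with no gene in the annotation, left out of the report's counts, moved too: 221 were higher and 240 lower in RNAi at stage 9, and 151 were higher and 842 lower at stage 12. The poly-A spikes, control RNAs added before labelling, had geometric mean signals of 335 in RNAi and 529 in ZH11 at stage 9, a ratio of 0.633, and of 694 and 494 at stage 12, a ratio of 1.405.

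Of the 1122 genes lower in RNAi at stage 12, 830 were higher at stage 12 in ZH11. The shared array gave at most 477 in simulations, which held no stage effect and so cannot size its part. Degraded RNA would raise the 3-prime to 5-prime ratios of the control genes on the RNAi array, and the higher of the RNAi over ZH11 ratios of these was 0.999, while another scaling still left at least 962 genes lower, so both are argued against as the whole cause, although scaling cannot be told apart for EXPB8, whose log2 ratio near the 2-fold threshold went from -1.02 to -0.87 and -0.92 while 3 other beta-expansins stayed past it. Spikelets somewhat younger in RNAi stay open and cannot be told apart. On the deposited scale, the 763 genes at least 4-fold lower at stage 12 by the mean of both genotypes had a median log2 ratio of 0.40 (quartiles 0.09 and 0.70). This lay between the bounds of 0.5 and 0.25 that were set, but it was 0.54 and 0.53 under median and quantile scaling. Those at least 4-fold higher, 1004 genes on the deposited scale, which younger spikelets would lower, had a median of -0.07, or 0.10 and 0.04 with these scalings. Their quartiles on the deposited scale were -1.53 and 0.35, so part of them stood well below ZH11. A smaller share of pollen RNA would lower pollen genes by one factor, and the 321 genes seen by ZH11 signal only at stage 12 had an interquartile range of 4.84, past the bound of 2 written against it; that bound was wrong because 175 of the ratios are bounds set by the floor and the genes were picked by signal from whole spikelets, with nothing to tell pollen genes from others, so this cannot be told apart either. An effect of the kinase on pollen genes, the biological explanation the design names, was not separated from these and stays open, untested.

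Of 33 jasmonate genes, 10 were higher in RNAi at stage 9 and 1 was lower. RNAi spikelets older than those of ZH11 are argued against as the whole cause. The 587 genes at least 4-fold higher at stage 12 by the mean of both genotypes (1004 in the stage 12 check) had a median log2 ratio of -0.24 at stage 9. The cyclins and DNA replication genes, 17 of which were lower at stage 12 in ZH11, lay at percentile 100 at stage 9. The 936 genes at least 4-fold lower, which older spikelets would lower, had a median of -0.07. Of the 504 genes higher in RNAi at stage 9, 174 were higher and 87 lower at stage 12 in ZH11, against 78.9 and 72.5 for independent lists. Both lists hold the ZH11 stage 9 array, and simulations without a stage effect gave 165 and 4.63, so these overlaps cannot decide it. A general stress at collection could be a source and cannot be told apart: the heat shock list lay at percentile 100 of matched random lists, but that was known when the explanation was written, and each genotype was collected as 1 sample per stage. An effect of the silenced kinase stays open as well, untested.

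Tapetum genes were split at stage 9, with OsC6 and EAT1 lower and PTC1 higher in RNAi. RNAi spikelets slightly younger at stage 9 may contribute and cannot be told apart. The cyclins and DNA replication genes (percentile 100) go with it. The 587 genes at least 4-fold higher at stage 12 by the mean of both genotypes had a median of -0.24, short of the bound of -0.5 set for it. The 936 genes at least 4-fold lower, which it would raise, had one of -0.07. These sets are not those of the stage 12 check, which held 1004 and 763 genes. An effect of the kinase on the tapetum stays open as well, untested.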

How the results depend on the processing

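Counts over all non-control probe sets and the lists before the removal of 20 members were chosen after seeing the data, as were the PP2C, RAB16 and LEA, and WRKY lists, the stage 12 noise of the simulations and the choice of genes seen only at stage 12; the other alternatives were set beforehand. Leaving out a replicate was not possible, and no count could be repeated without an array in doubt, because each group was 1 array. No paired analysis was possible because each group held 1 array and no result came from a test. Each count of genes stayed within 1.5 times its main value under both other floors, the pseudocount, both scalings, the mean over probe sets and the omission of cross-matching probe sets. At a 3-fold threshold, fewer genes can pass: 234 were higher and 128 lower in RNAi at stage 9, 114 and 670 at stage 12, 1685 and 1543 at stage 12 against 9 in ZH11, 1347 and 1401 in RNAi, and 1177 differed between stages. With noise from stage 12, which holds the differences themselves, the simulated overlaps, all without a stage effect, were 436, 250 and 15.9 against 217, 163 and 5.31. Of genes seen only at stage 12, chosen by the RNAi signal 4 were lower in RNAi, and chosen by the mean of both genotypes 68, against 228 by the ZH11 signal. Over all probe sets, of which there are more than genes, 803 were higher and 633 lower at stage 9, 2119 lower at stage 12, 4678 higher and 4570 lower between stages in ZH11, 3800 and 4508 in RNAi, 4270 differed between stages, and 1588 were lower in RNAi at stage 12 and higher at stage 12 in ZH11. Of the list medians, 664 values stayed within 0.25 of the main one and 23 moved further. Among lists outside the central 95% of random lists 1 changed sign, the ribosomal proteins at stage 12, with 0.0064 under median scaling. The cause was not tested. Changes of sign in lists inside that range are not in this count. Under median scaling they included the tapetum, actin, aquaporin, calcium-dependent protein kinase and cyclin lists at stage 12. Between stages they included the peroxidase list in ZH11 and the calcium channel and heat shock lists in RNAi. At 2 times the floor, medians for stage 12 against 9 in ZH11 were -3.60 for the tapetum list, 0.43 for sugar, 0.31 for jasmonate, -0.54 for cellulose synthase, -0.26 for RAB16 and LEA and 0.00 for WRKY genes; in RNAi they were -2.47 for the tapetum and -0.11 for the meiosis list, and for the genotypes 0.34 for RAB16 and LEA genes at stage 12 and 0.75 for WRKY genes at stage 9. At 0.5 times the floor they were -1.04 (RAB16 and LEA, ZH11) and -0.43 (alpha-expansins, RNAi), and with a pseudocount -3.92 (tapetum, ZH11), -0.80 (RAB16 and LEA, ZH11) and -0.28 (alpha-expansins, RNAi). Without cross-matching probe sets they were -0.80 for the tapetum at stage 9, -0.61 for beta-expansins at stage 12 and 1.40 for sugar in ZH11. With the mean over probe sets they were 0.34 for jasmonate and 0.10 for starch in ZH11, the latter from -0.21, and -0.56 for calcium channels in RNAi. Before the removal of members the ROP list stood at -1.47 in ZH11 and -1.11 in RNAi. Of the named genes' genotype ratios past 2-fold, 818 values stayed within 0.5 and 91 moved further, and none changed sign, but 9 fell within 2-fold at 2 times the floor, 8 with a pseudocount, 6 under median scaling and 5 after quantile normalization. So did 1 with the mean over probe sets (CHS1 at stage 9, log2 ratio -0.93) and 1 without cross-matching probe sets (NifU1 at stage 12, log2 ratio 0). The bound for OsCPK21 at stage 12 followed the floor, from a log2 ratio of -4.26 at 2 times the floor to -6.26 at 0.5 times. Signals near the floor limit the size of a ratio, not whether the bright array was above it.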

Other observations

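The lists of protein phosphatases, RAB16 and LEA genes and WRKY factors were chosen after single-gene values were seen, and no explanation was tested for the values in this part.

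Among 55 PP2C protein phosphatases, a family that includes negative regulators of abscisic acid signalling, 7 were higher in RNAi at stage 9 and 7 at stage 12, OsPP2C12 was lower at stage 9 (log2 -1.21), and OsPP2C29, PP2C30, OsPP2C32, OsPP2C35, OsPP2C61 and PP2C68 were higher at both. With a pseudocount PP2C30 fell within 2-fold at stage 9. Under both other scalings 9 of the phosphatases were higher at stage 12. The list's medians were small, 0.07 at stage 9 (percentile 99.9) and 0.09 at stage 12 (percentile 86.7). At stage 12 OsPP2C75, OsPP2C59, PP2C13 and OsPP2C15 were lower, with log2 ratios of -2.37, -2.31, -2.22 and -2.11. Of 6 RAB16 and LEA genes, which accumulate in drying tissues, LEA19 and RAB16B were higher and rab25 and RAB16C lower at stage 9, and RAB21 and RAB16B were higher and RAB16D lower at stage 12, with medians of 0.11 and 0.79 (percentile 99.9, and 0.34 at 2 times the floor). RAB21, RAB16B, RAB16C and RAB16D lie side by side by locus number and did not go together at stage 12: RAB21 had a log2 ratio of 3.82, RAB16B a bound of 1.53, RAB16C 0.65 and RAB16D a bound of -2.10. Of 5 WRKY genes, WRKY71, WRKY24 and WRKY76 were higher at stage 9, with log2 ratios of 4.99, 2.13 (a bound) and 1.05, and WRKY24 at stage 12, with 1.25. Other genes with an informative symbol outside the naming rule that were higher at both stages were SAT4 (5.44-fold and 2.69-fold), the potassium channel AKT1 (3.35-fold and 2.15-fold), TPP7, of trehalose synthesis (3.55-fold and 3.37-fold), the homeobox gene Hox22 (2.54-fold and 2.12-fold) and BIMK1 (2.26-fold and 2.32-fold), and those lower at both were NAC010 (2.59-fold and 3.39-fold) and BC1L6 (2.35-fold and 3.46-fold).

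Among 46 cyclins and DNA replication genes 4 were higher in RNAi at stage 9, CycB1-1 by 2.76-fold, CYCD2-2 by 2.28-fold, OsMCM6 by 2.16-fold and MCM3 by 1.08 on the log2 scale, and the median was 0.17, above all 10000 matched random lists. At stage 12 CYCD2-2 was higher and CDKF-4 (2.91-fold) and CYCA2-1 (2.21-fold) lower, and the median of -0.04 turned sign under both other scalings. CYCA2-1 fell within 2-fold under both of these scalings, and CYCD2-2 at 2 times the floor. Between stages 17 of the 46 genes were lower at stage 12 in ZH11 and 23 in RNAi. Among 11 alpha-expansins EXP2 was 2.44-fold lower at stage 9, and EXP32, EXP26 and EXP8 were at least 24.6-fold, 22.8-fold and 11.2-fold lower at stage 12, while the list's median there was 0.21 (percentile 92.9). Among 25 aquaporins NIP4-1 and the silicon transporter Lsi6 (2.79-fold) were lower at stage 9. At stage 12 TIP2 (at least 10.9-fold), OsSIP2;1 (3.20-fold), TIP1 (3.11-fold) and OsPIP2;7 (log2 -1.19) were lower and OsPIP1;3 was higher. Of 27 cellulose synthase family genes CSLC9 (6.65-fold) and CSLD5 (at least 5.47-fold) were lower at stage 12 and none passed 2-fold at stage 9, and 12 were lower between stages in ZH11 and 11 in RNAi.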
